A study of Mus musculus with 4 samples.

How the data were processed

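Total RNA of whole skin from 4 embryos, 2 controls and 2 mutant littermates, was hybridised to Affymetrix mouse 430 2.0 arrays, 1 embryo per array. The deposited value tables hold 1 signal intensity per probe set and array, made by the authors with GCOS and MAS5 (no version of either given, per the labels); the scaling target is not stated in the files used here, and no detection calls or probe-level data were used. All values are positive and on a linear scale, and the array medians lie between 27.7 and 32.0, so the values were taken as scaled per array and were not normalized again. A second deposited table is the authors' list of changed probe sets. Per the file headers, its fold column is the ratio of mutant over control, and its probe sets were called Present in at least 2 of 4 arrays, had an uncorrected p under 0.01 and changed at least 2-fold; the header names GCRMA. The table's 4 further columns hold, as deposited, a ratio of each sample to the mean of the 2 control columns; they do not give the fold column, so they were compared with it and used for nothing else. The scanner settings files name 1 day, 1 station and 4 modules, 1 per array, and so no batch that could be entered in a model. They also give epidermis as the sample type, where the labels give epidermis and dermis; the dermal collagen gene Col3a1 read 7229 to 9491 on the 4 arrays.

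The value tables hold 45037 probe sets besides 64 array controls. Gene names came from the platform's table of probe sets and genes, with symbols updated by gene identifier from a reference gene table (assembly GRCm38.p6, used for names only): 34945 probe sets matched 1 gene, 932 matched several and 9160 are unnamed here. Of 541 genes in the 28 lists, 2 had no match in the reference table. A gene with several probe sets was represented by the one with the highest mean signal. Of 5252 genes with more than 1 tested probe set, 349 had some called and some not, and 1, Malat1, had probe sets called in opposite directions.

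Signals were put on the scale log2(signal + 7.7), the offset being the percentile 25 of all values over the 4 arrays. This shrinks fold changes of dim genes. Probe sets whose mean signal reached the median of all probe sets, 31.1, were tested, 22519 in all, of which 20182 have 1 gene name and represent 11549 genes. A gene dim in only 1 group could pass this filter through the other group, so the filter favours changes in the counts of every list. Mutant and control groups were compared in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a variance trend, two-sided moderated test), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of adjusted p 0.05. Means and SDs are of linear signals (n = 2 per group); log2 fold changes and SEs are from the model. Leaving out 1 array leaves its group with a lone sample, which the model takes to vary like the other group. The number of arrays limits the precision.

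Lists of marker and pathway genes were written from general knowledge: Wnt targets, Wnt ligands and modulators, hair placode, hair shaft and matrix, epidermal differentiation, basal epidermis, hedgehog, BMP and TGF-beta, Eda and NF-kappaB, FGF, Notch, dermal condensate, dermis, melanocyte, Merkel cell and simple epithelium, muscle, nerve and Schwann cell, endothelium, erythroid cell, macrophage and mast cell, adipocyte, cartilage and bone, proliferation, cell cycle exit, immediate early and stress, and hypoxia and glycolysis. The lists overlap in 29 genes. These 26 were tested with camera (preset correlation 0.01, 1 probe set per gene, adjusted over the lists), which compares a list's members with all other genes. With the correlation estimated from these 4 arrays instead, none of the 16 calls holds. Sex-linked genes (4 tested) and the genes of the mutation itself (Ctnnb1 and Krt14) were kept out of that test. A member was counted as changed by its limma adjusted p over all probe sets, and also with p adjusted over the list alone.

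The genes named in the text followed a rule: the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with groups that do not overlap, up to 4 called members per list with the largest change (2 where none passed), and Ctnnb1 and Krt14. The rule names 107 genes, of which 101 passed. Of these, 23 lost their call in at least 1 of the 4 fits that left out 1 array, and 0 changed sign. Groups, model, lists, rule and alternatives were fixed before the data were examined; the families of Irx, Hox, Dlx, Krtap, Unc5, semaphorin and smooth muscle genes in the closing section were chosen afterwards.

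The pipeline was tested on simulated data of 22519 probe sets in 5 runs, with 100 changed probe sets per fold in each. At 2-fold 88% were recovered and at 4-fold 100%, all with the right sign, and 8.65% of the calls were false, above the 5% that the threshold aims at. Each simulated probe set had the typical spread of its signal level. Probe sets that vary more were thus not simulated, such as those of Xist (SE 1.85) and Col2a1 (SE 1.53), which did not pass. For such probe sets the recovery is too high. Of 20 simulated lists of 25 genes, camera called 100% when they were shifted by 0.5 on the log2 scale and 5% when they were not. These calls were taken at an unadjusted p under 0.05. The simulated genes varied independently, whereas the estimated correlation within a measured list reached 0.94 (cartilage and bone). The 5% thus holds for uncorrelated genes only and does not test the calls of the measured lists.

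Alternatives tried were no offset and an offset at the median (30.4), quantile normalization and median centring, no filter and a filter at the percentile 75 of signal, no variance trend and a robust one, the sample number as a block, each array left out, an adjusted p under 0.1, an added 2-fold limit, 1 probe set per gene or the mean of its probe sets, no probe sets prone to cross-hybridisation, camera with an estimated correlation, and fry.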

Results

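Transcripts were measured in whole skin, epidermis and dermis together, of mouse embryos at stage E14.5, when the first hair follicles form. The 4 arrays hold skin of 2 control embryos and of 2 mutant littermates. The mutants carried KRT14-Cre, a recombinase active in keratinocytes, and 1 Ctnnb1 allele from which Cre removes the exon with the degradation signals of beta-catenin. The epithelium of such embryos makes a stabilised beta-catenin, the effector of the Wnt pathway. The median signal of an array lay between 27.7 and 32.0 and the mean between 219 and 227. Across probe sets, which are not independent replicates, the log2 signals correlated with r = 0.979 between the controls and r = 0.981 between the mutants. Between a control and a mutant, r lay between 0.923 and 0.941. The log2 ratio of 3' to 5' control probe sets, a sign of RNA integrity, lay between -0.52 and -0.39 for Gapdh and between 0.28 and 0.38 for beta-actin, with the groups overlapping for Gapdh and the mutants lower for beta-actin. Spiked-in poly-A RNA was 2.23-fold higher in the controls over 12 probe sets and 18S RNA 2.07-fold higher over 3, while the hybridization spikes differed by -0.04 on the log2 scale over 9. The amount of spike RNA per sample is not known here, and all changes are given relative to the signal of the whole array. On a scale set by the poly-A spikes every log2 change would be higher by 1.16, so falls smaller than that would turn into rises. The number of arrays limits the precision of every value, and a two-sided permutation test of 2 against 2 arrays cannot give a p under 0.333.

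The comparison of mutant with control skin asks which transcripts change when beta-catenin is active throughout the embryonic epithelium. Hair keratin and keratin-associated protein genes were 11 of the 12 genes with the largest rise. Krt33a, a hair keratin, had a signal of 5.12 ± 6.39 (SD, n = 2) in control skin and 2974 ± 406 (SD, n = 2) in mutant skin, a log2 fold change of 7.95 (SE 0.33, adjusted p = 0.000119). Krtap8-1, a keratin-associated protein of the hair shaft, went from 15.5 ± 11.5 to 4282 ± 1040 (SD, n = 2 per group), a log2 fold change of 7.61 (SE 0.34, adjusted p = 0.000147). The other 10 of the 12 genes with the largest rise were the hair keratins Krt33b, Krt34 and Krt35, the keratin-associated proteins Krtap1-5, Krtap7-1, Krtap11-1, Krtap13-1, Krtap16-3 and Krtap22-2, and the predicted gene Gm10229. Their log2 fold changes ran from 6.43 for Krtap1-5 to 7.08 for Krt33b. The control signals of these 12 genes averaged 15.5 or less, under the median of every array, so the size of their folds depends on the offset added before the logarithm.

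The 12 genes with the largest fall included 4 of the list of epidermal differentiation, Krt1, Krt10, Krt77 and Them5. Krt1 and Krt10, the keratin pair of the suprabasal layers, fell by 5.50 (SE 0.25, adjusted p = 0.000149) and by 4.52 (SE 0.18, adjusted p = 0.000104) on the log2 scale. The signal of Krt1 was 2185 ± 451 in controls and 41.5 ± 16.3 in mutants, and that of Krt10 was 4900 ± 1041 and 206 ± 34.5 (SD, n = 2 per group). Krt77, a further suprabasal keratin, fell by 5.32 on the log2 scale. The rest of the 12 largest falls were Gsta2, a glutathione transferase, the thioesterase Them5, Sdr16c5 and Sdr16c6, which encode short-chain dehydrogenases, the serpin Serpinb12, Cpxm2, the transcription factor Irx2, the Wnt agonist Rspo1, and Capns2, a calpain subunit. These 9 had log2 fold changes from -4.42 for Gsta2 to -3.08 for Capns2. The mutant means of Gsta2, Sdr16c5 and Sdr16c6 lay under the offset, so the size of their falls depends on it.

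**Figure D1:**
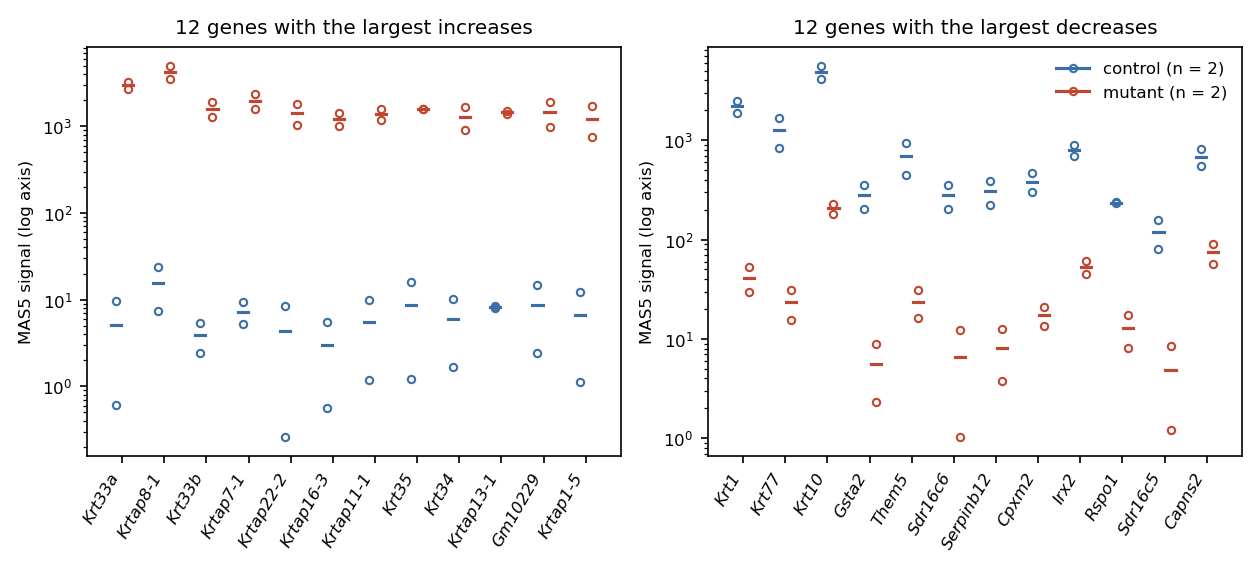
MAS5 signal (log axis) in each of the 4 arrays of the 12 genes with the largest rise and the 12 with the largest fall. Blue circles are control arrays, red circles mutant arrays and bars group means; Krt33a reads 9.64 and 0.60 in the controls and 3261 and 2687 in the mutants, and the means of Krt1 are 2185 in the controls and 41.5 in the mutants.

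Of 22519 probe sets tested, 1583 (7.03%) passed the limma threshold, 923 of them higher and 660 lower in mutant skin. At least 2-fold changes were called for 581 probe sets that rose and 370 that fell, and at least 10-fold changes for 73 and 14. Counted as genes with 1 probe set each, 573 rose and 436 fell. All 1583 had both mutant arrays on the same side of both controls, as did 54.3% of all tested probe sets, where chance gives 33.3%. The count was 982 without mutant replicate 1, 1008 without mutant replicate 2, 1187 without control replicate 2 and 2171 without control replicate 1. In mutant replicate 1, 8 genes of cartilage matrix were higher than in mutant replicate 2 by a median log2 difference of 4.14.

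Ctnnb1 itself had a signal of 5819 ± 683 in controls and 5985 ± 300 in mutants (SD, n = 2 per group), a log2 fold change of 0.04 (SE 0.12) that did not pass (limma adjusted p = 0.874). Its other probe sets had log2 fold changes of 0.32 (limma adjusted p = 0.155) and 0.26 (limma adjusted p = 0.171), and did not pass either. Where its probe sets lie relative to the removed exon is not known here, so these values do not test whether the exon was removed. Krt14, the keratin of basal keratinocytes whose promoter drives Cre, had a signal of 2184 ± 486 in controls and 1190 ± 362 in mutants (SD, n = 2 per group). Its log2 fold change of -0.89 (SE 0.23) did not pass (limma adjusted p = 0.0753), but did without control replicate 1 (adjusted p = 0.0338) and without mutant replicate 2 (adjusted p = 0.0115). Of the X- and Y-linked genes used to read sex, Xist had a signal of 3376 in mutant replicate 2 and of 10.1 to 24.7 in the other arrays. Eif2s3y, on the Y chromosome, read 16.1 in mutant replicate 2 and between 453 and 502 in the others. Mutant replicate 2 was thus the only array with a female pattern, and of the 4 sex-linked genes tested none passed between the groups.

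Genes of the hair matrix, hair shaft and inner root sheath rose together. Of 31 measured members, 28 rose, 1 fell and 2 did not pass, and adjusted over the list alone 28 rose and 1 fell. Most that rose had control means under the filter of 31.1 and were tested only because of their mutant signals. Members dim in both groups were not tested, so the filter favours rises in this count. The median log2 fold change was 3.97 (camera adjusted p = 2.01e-30 with a preset correlation, adjusted p = 0.164 with an estimated correlation), a size that depends on the offset where controls are dim. The member that fell was Gata3, a transcription factor of the inner root sheath and of the interfollicular epidermis, with a log2 fold change of -2.60; it was chosen after its values were seen.

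Genes of epidermal differentiation fell as a list, and so did genes of basal keratinocytes. Of 30 measured differentiation genes 14 fell, none rose and 16 did not pass, with a median log2 fold change of -1.13; adjusted over the list alone 16 fell. The set test gave a camera adjusted p = 9.63e-08 (adjusted p = 0.488 with an estimated correlation). The controls stood apart on these genes, control replicate 2 above control replicate 1 by a median of 0.83 for differentiation and 0.48 for basal genes on the log2 scale, and without control replicate 2 the median change of the differentiation genes was -0.68. Of 22 measured basal keratinocyte genes 9 fell and 13 did not pass, with a median of -0.71, and adjusted over the list alone 15 fell and 2 rose. Their camera adjusted p was 8.84e-06 (adjusted p = 0.488 with an estimated correlation). Col7a1 and Col17a1, which anchor basal cells to the dermis, fell by 1.97 and 1.62 on the log2 scale, and the basal keratin Krt15 by 2.67. The adhesion gene Cdh1 fell by 1.54. Without control replicate 2 the calls of Krt15 (adjusted p = 0.0761) and Cdh1 (adjusted p = 0.0571) ended, as they did without the filter (adjusted p = 0.0745 and 0.0606) and without the variance trend (adjusted p = 0.0659 and 0.0568), and that of Krt15 with a robust trend (adjusted p = 0.194).

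**Figure D2:**
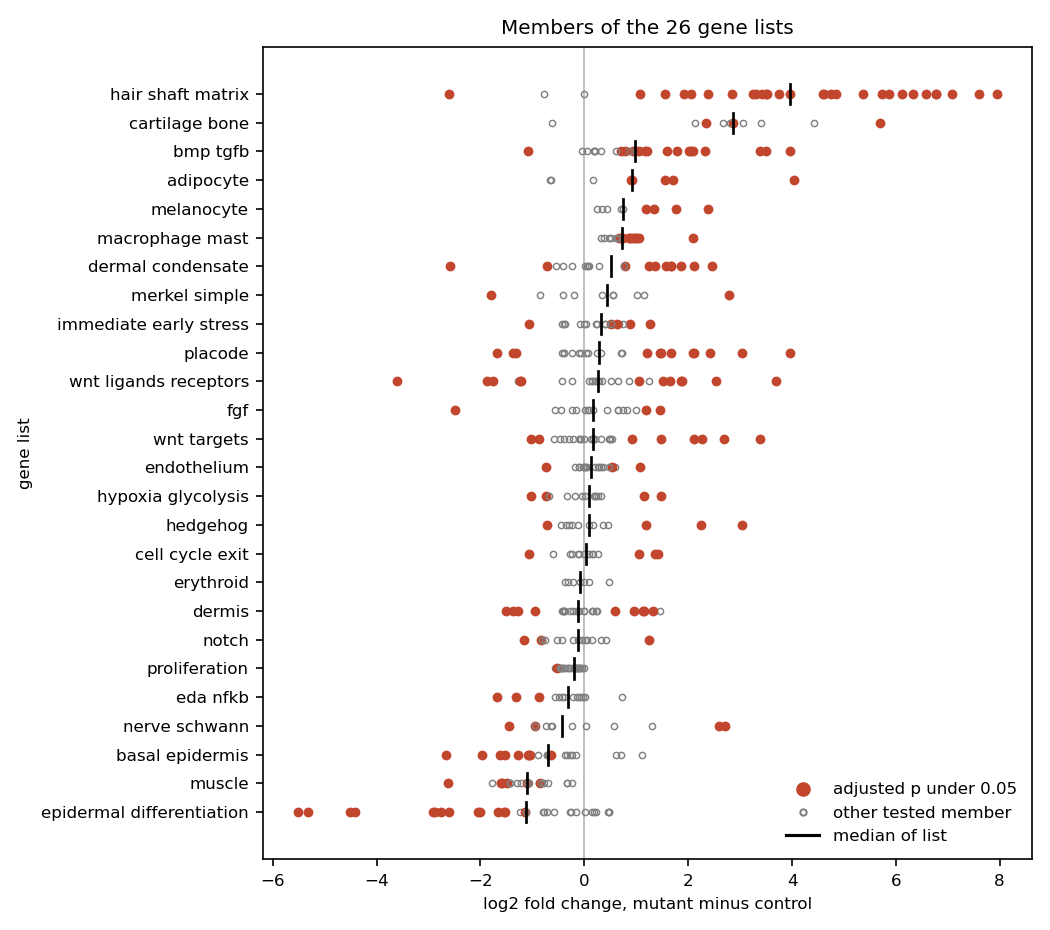
Log2 fold change, mutant over control, of each measured member of the 26 gene lists (y axis). Filled points passed the limma threshold, open points did not, and bars mark list medians. Hair shaft genes have the highest median, 3.97, and epidermal differentiation genes the lowest, -1.13.

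More Wnt target genes rose than fell in mutant skin, and most did not pass. Bambi, which encodes a decoy receptor for BMP ligands, went from 118 ± 5.20 to 1312 ± 92.8 (SD, n = 2 per group), a log2 fold change of 3.39 (SE 0.12, adjusted p = 6.56e-05). Dkk1, Notum and Wif1, inhibitors of the Wnt pathway itself, rose by 2.70, 2.26 and 2.12. Axin2 and Lef1, chosen after their values were seen, had log2 fold changes of 0.13 (adjusted p = 0.693) and -0.10 (adjusted p = 0.841). Of 26 measured Wnt target genes 6 rose, 2 fell and 18 did not pass, with a median of 0.16, and adjusted over the list alone 8 rose and 4 fell. The 2 that fell, Nkd2 and Tnfrsf19, were chosen after their values were seen. Nkd2 lost its call without control replicate 2 (adjusted p = 0.0760), mutant replicate 1 (adjusted p = 0.0932) or mutant replicate 2 (adjusted p = 0.0587), and Tnfrsf19 without control replicate 2 (adjusted p = 0.0523) or mutant replicate 1 (adjusted p = 0.0591). The list's camera adjusted p was 0.0299 (adjusted p = 0.518 with an estimated correlation), and its call ended without control replicate 1 (adjusted p = 0.282), without mutant replicate 2 (adjusted p = 0.0735) and without the filter on dim probe sets (adjusted p = 0.0708). Over 16 alternatives its adjusted p ran from 0.00140 to 0.518.

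Wnt ligands and secreted modulators changed in both directions. Rspo2, a Wnt agonist, rose from 18.8 ± 21.6 to 273 ± 6.76 (SD, n = 2 per group; log2 fold change 3.70, adjusted p = 0.0123), while its relative Rspo1 fell from 236 ± 3.53 to 12.9 ± 6.65 (log2 fold change -3.60, adjusted p = 0.000882). The Rspo2 controls read 34.1 and 3.53, the latter under the offset, so the size of its fold depends on the offset and on the control taken. The inhibitors Frzb and Dkk2 rose by 2.53 and 1.88. Of 27 measured members 7 rose, 5 fell and 15 did not pass, and adjusted over the list alone 10 rose and 6 fell. Besides Rspo1 the members that fell were Wnt7b, Sfrp5, Wnt4 and Wnt3a, chosen after their values were seen; Wnt3a lost its call without control replicate 2 (adjusted p = 0.135), mutant replicate 1 (adjusted p = 0.103) or mutant replicate 2 (adjusted p = 0.124). The median was 0.26 and the camera adjusted p 0.0312 (adjusted p = 0.436 with an estimated correlation). The list's call ended without mutant replicate 1 (adjusted p = 0.0556), without the filter (adjusted p = 0.107) and without the variance trend (adjusted p = 0.0541), with a range of 1.0e-04 to 0.436 over 16 alternatives.

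Genes of the hair placode, the epithelial thickening that starts a follicle, rose more often than they fell. Msx2 went from 20.8 ± 3.74 to 437 ± 12.7 (SD, n = 2 per group; log2 fold change 3.97, SE 0.17, adjusted p = 0.000121). Shh, the signal from placode to dermis, rose by 3.03 on the log2 scale, Dlx3 by 2.42 and Sox9 by 2.11. Of 24 measured members 9 rose, 3 fell and 12 did not pass, with a median of 0.28, and adjusted over the list alone 9 rose and 4 fell. The 3 that fell were Edaradd, Ltb and Bcl11b, the latter chosen after its values were seen, and Ltb lost its call without control replicate 2 (adjusted p = 0.0973) or mutant replicate 1 (adjusted p = 0.104). The camera adjusted p was 0.00683 (adjusted p = 0.470 with an estimated correlation). Msx2, Dlx3, Sox9 and Fgf20 had control means under the filter of 31.1 and were tested only because of their mutant signals. The filter thus favours rises of such dim members.

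Genes of the BMP and TGF-beta pathways rose together. Of 28 measured members 16 rose, 1 fell and 11 did not pass, with a median of 0.97, and adjusted over the list alone 21 rose and 1 fell. The camera adjusted p was 7.48e-14 (adjusted p = 0.164 with an estimated correlation). The homeobox targets Msx1 and Msx2 rose by 3.49 and 3.97 and the ligand Bmp5 by 2.33. The receptor Bmpr1b fell by 1.08, was chosen after its values were seen, and lost its call without control replicate 2 (adjusted p = 0.102), mutant replicate 1 (adjusted p = 0.0915) or mutant replicate 2 (adjusted p = 0.111). In mutant replicate 1, 8 cartilage matrix genes exceeded mutant replicate 2 by a median of 4.14 on the log2 scale. Without mutant replicate 1 the median of the BMP and TGF-beta genes was 0.92, so their rise did not rest on that array.

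The hedgehog pathway had members that rose without passing as a list. Hhip and Ptch1, both targets of hedgehog signalling, rose, Hhip by 2.24 on the log2 scale and Ptch1 from a mean signal of 750 to 1723, and Gas1, a co-receptor, fell by 0.71. Of 13 measured members 3 rose, 1 fell and 9 did not pass, and adjusted over the list alone 3 rose and 1 fell (median 0.10, camera adjusted p = 0.281). Gas1 lost its call without control replicate 1 (adjusted p = 0.0947), control replicate 2 (adjusted p = 0.0939) or mutant replicate 2 (adjusted p = 0.186).

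In the Eda and NF-kappaB list 3 genes fell. Edaradd, the adaptor of the Eda receptor, fell by 1.69 on the log2 scale, Ltb by 1.32 and the ligand gene Eda by 0.87. Of 14 measured members these 3 fell and 11 did not pass, with a median of -0.30, and adjusted over the list alone 5 fell. The camera adjusted p was 0.00727 (adjusted p = 0.470 with an estimated correlation). Eda lost its call without any 1 of the arrays (adjusted p = 0.0505 to 0.170), and Ltb without control replicate 2 (adjusted p = 0.0973) or mutant replicate 1 (adjusted p = 0.104).

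The FGF and Notch lists did not pass as lists. In the FGF list Fgfbp1, which releases FGF from the matrix, fell by 2.50, while Fgf20 rose by 1.47 and Etv4 from a mean signal of 24.5 to 65.0, and 14 of 17 members did not pass. Adjusted over the list alone 3 rose and 2 fell (median 0.18, camera adjusted p = 0.225). In the Notch list the target Hey1 rose by 1.25, Nrarp fell by 1.16 and the ligand Jag2 fell by 0.83, and 12 of 15 members did not pass. Adjusted over the list alone 1 rose and 6 fell (median -0.13, camera adjusted p = 0.225). Fgf20 lost its call without control replicate 1 (adjusted p = 0.0529), mutant replicate 1 (adjusted p = 0.0531) or mutant replicate 2 (adjusted p = 0.134). Etv4 lost it without control replicate 1 (adjusted p = 0.0527), mutant replicate 1 (adjusted p = 0.0909) or mutant replicate 2 (adjusted p = 0.134), and Jag2 without mutant replicate 1 (adjusted p = 0.111) or mutant replicate 2 (adjusted p = 0.0851).

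Among dermal markers, read in whole skin, those of the dermal condensate, the fibroblast cluster under each placode, rose more often than they fell. General fibroblast genes went both ways. Crabp1, a retinoic acid binding protein of fibroblasts, fell from 5751 ± 416 to 958 ± 73.7 (SD, n = 2 per group; log2 fold change -2.58, SE 0.11, adjusted p = 0.000135). Foxd1 rose by 2.47 on the log2 scale, Wif1 by 2.12 and Rspo3 by 1.86. Of 20 measured condensate genes 9 rose, 2 fell and 9 did not pass, with a median of 0.52, and adjusted over the list alone 10 rose and 3 fell. The camera adjusted p was 0.00137 (adjusted p = 0.422 with an estimated correlation). The other condensate gene that fell, Tbx18, was chosen after its values were seen and lost its call without control replicate 2 (adjusted p = 0.0693) or mutant replicate 2 (adjusted p = 0.123). Of 26 measured fibroblast genes 5 rose, 4 fell and 17 did not pass (median -0.11, camera adjusted p = 0.502), and adjusted over the list alone 6 rose and 8 fell. That median has no stable sign, running from -0.25 without control replicate 2 to 0.03 without control replicate 1. Twist2 fell from a mean signal of 2130 to 760, Dpt and Twist1 by 1.38 and 1.27 on the log2 scale, and Meox2 rose by 1.32. The others, chosen after their values were seen, were Fbln1, which fell by 0.95, and Ogn, Fbln2, Mfap4 and Prrx1, which rose by 1.14, 1.13, 0.95 and 0.60. Fbln2 lost its call without mutant replicate 1 (adjusted p = 0.0555), and Prrx1 without mutant replicate 1 (adjusted p = 0.0826) or mutant replicate 2 (adjusted p = 0.0653).

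Among other cell types of the skin, markers of melanocytes, macrophages and mast cells, and adipocytes rose as lists with the preset correlation, though not every member passed. The melanosome genes Mlana, Gpnmb, Pmel and Dct rose by 2.38, 1.77, 1.34 and 1.19, and 5 of 9 measured melanocyte genes did not pass (median 0.74, camera adjusted p = 2.45e-05, adjusted p = 0.474 with an estimated correlation). Adjusted over the list alone 6 melanocyte genes rose, and Pmel and Dct lost their calls without the filter (adjusted p = 0.0545 and 0.0531). Mcpt4, a mast cell protease, rose by 2.09, the complement genes C1qc and C1qa by 1.05 and 0.97, and the lysozyme gene Lyz2 by 1.02. Of 18 measured macrophage and mast cell genes 11 rose and 7 did not pass (median 0.72, camera adjusted p = 1.08e-10, adjusted p = 0.422 with an estimated correlation), and adjusted over the list alone 16 rose. C1qa lost its call without mutant replicate 1 (adjusted p = 0.0529) or mutant replicate 2 (adjusted p = 0.0558), and Lyz2 without mutant replicate 2 (adjusted p = 0.0585), and both lost it without the filter (adjusted p = 0.0595 and 0.0605) or the trend (adjusted p = 0.0577 and 0.0597). Adipoq, the fat cell hormone adiponectin, rose from 7.14 ± 2.59 to 236 ± 34.3 (SD, n = 2 per group; adjusted p = 0.000335), with a fold whose size depends on the offset. Fabp4, Pparg and Cd36 rose by 1.71, 1.56 and 0.93, as did Lpl by 0.90, which was chosen after its values were seen. Of 8 measured adipocyte genes 5 rose and 3 did not pass, and adjusted over the list alone 5 rose and 2 fell (median 0.91, camera adjusted p = 0.00125, adjusted p = 0.422 with an estimated correlation).

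Skeletal muscle genes fell. Myh7 and Myh3, both myosin heavy chains, fell by 2.61 and 1.58 on the log2 scale, the troponin gene Tnnt2 by 1.61 and the titin gene Ttn by 1.48. Of 21 measured muscle genes 6 fell and 15 did not pass, with a median of -1.10 (camera adjusted p = 3.15e-08, adjusted p = 0.474 with an estimated correlation), and adjusted over the list alone 17 fell. The median was -1.59 without mutant replicate 1 and -0.70 without mutant replicate 2. Muscle genes also differed within the groups. The median log2 difference was 0.90 for mutant replicate 1 minus mutant replicate 2 and -0.40 for control replicate 2 minus control replicate 1. How much muscle each sample held was not measured, so its part in the fall was not tested. Ttn lost its call without control replicate 1 (adjusted p = 0.0693) or control replicate 2 (adjusted p = 0.0550). Myh7, Myh3 and Ttn lost theirs without the filter (adjusted p = 0.0656, 0.0614 and 0.0882), without the variance trend (adjusted p = 0.0570, 0.0572 and 0.0782) and with a robust trend (adjusted p = 0.0894, 0.0521 and 0.0775).

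Cartilage and bone genes stood apart in mutant replicate 1. Col2a1, the main collagen of cartilage, had a signal of 1948 in mutant replicate 1, 37.7 in mutant replicate 2, and 12.5 and 1.71 in the controls; it was chosen after its values were seen and did not pass (adjusted p = 0.146), but did without mutant replicate 2 (adjusted p = 3.2e-05). Ibsp, a protein of mineralising bone, read 741 and 321 in the mutants and 2.12 and 1.58 in the controls, and rose (adjusted p = 0.000687); its control signals lie under the offset, so no size is given for its fold. Sp7, an osteoblast transcription factor, rose by 2.35. Col11a1 rose by 2.87, but lost its call without control replicate 2 (adjusted p = 0.103) or mutant replicate 1 (adjusted p = 0.0510), with a robust trend (adjusted p = 0.252), without the trend (adjusted p = 0.0890), the filter (adjusted p = 0.104) or the offset (adjusted p = 0.0511), and with the mean of its probe sets (adjusted p = 0.0564). Of 11 measured members these 3 rose and 8 did not pass, and adjusted over the list alone 4 rose. The median was 2.87, against 1.05 without mutant replicate 1 and 4.60 without mutant replicate 2 (camera adjusted p = 0.000114, adjusted p = 0.488 with an estimated correlation). Col2a1, Acan, Matn1, Matn3, Comp, Hapln1 and Ibsp read under the filter of 31.1 in both controls and were tested only because of their mutant signals. For Acan, Matn1, Matn3 and Comp this rested on mutant replicate 1 alone. The filter thus favours a rise of this list, also in the median without mutant replicate 1.

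**Figure D3:**
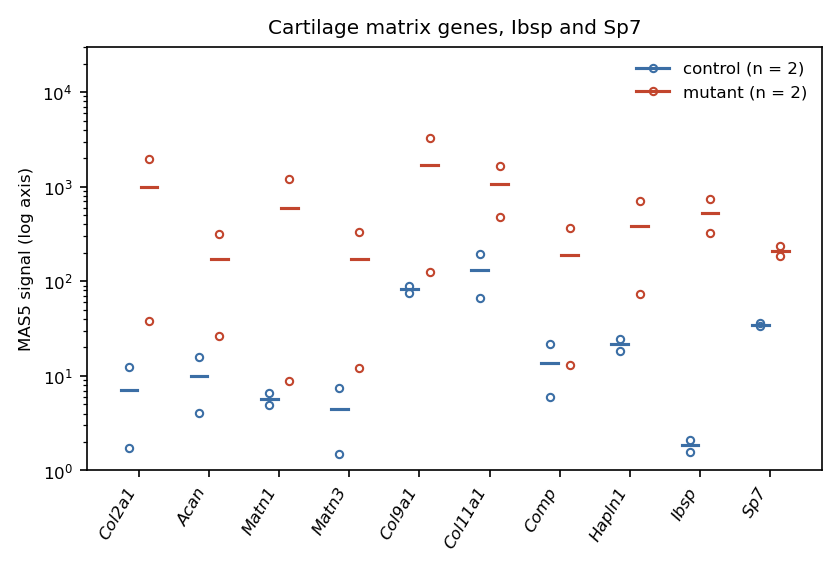
MAS5 signal (log axis) of 8 cartilage matrix genes and of the bone genes Ibsp and Sp7, with blue circles for control arrays, red circles for mutant arrays and bars for group means. Col2a1 reads 1948 in mutant replicate 1 and 37.7 in mutant replicate 2, while Sp7 reads 235 and 185.

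Markers of nerve, vessel, Merkel and red blood cells did not pass as lists. Tubb3, a neuronal tubulin, and S100b, a glial protein, rose by 2.71 and 2.59, while the Schwann cell genes Fabp7 and Erbb3 fell by 1.44 and 0.95. Of 12 nerve and Schwann cell genes these 4 passed and 8 did not, and the list's mean of 0.13 differs in sign from its median of -0.43 and its test (camera, down, adjusted p = 0.368). Adjusted over the list alone 3 rose and 5 fell, and S100b lost its call without the filter (adjusted p = 0.0539). Of 18 endothelial genes Tek and Ramp2 rose by 1.07 and 0.54, Flt4 fell by 0.74 and 15 did not pass, and adjusted over the list alone 2 rose and 1 fell (median 0.13, camera adjusted p = 0.0883). With the stricter filter on dim probe sets the endothelial list passed (adjusted p = 0.00982, the lowest of 16 alternatives, the highest being 0.470), as it did with fry by direction (adjusted p = 0.0451). Ramp2 lost its call without any 1 of the arrays (adjusted p = 0.0623 to 0.222), and Flt4 without control replicate 2 (adjusted p = 0.0805), mutant replicate 1 (adjusted p = 0.123) or mutant replicate 2 (adjusted p = 0.0947). Of 10 genes of Merkel cells and simple epithelia Krt23 rose by 2.79 and Isl1 fell by 1.79, and adjusted over the list alone 3 rose and 2 fell (median 0.45, camera adjusted p = 0.358). Krt23 lost its call without mutant replicate 2 (adjusted p = 0.0734), the offset (adjusted p = 0.0709), the filter (adjusted p = 0.0898) or the trend (adjusted p = 0.0715) and with a robust trend (adjusted p = 0.0949), and Isl1 without the filter (adjusted p = 0.0882), the trend (adjusted p = 0.0612), control replicate 1 (adjusted p = 0.0730) or mutant replicate 2 (adjusted p = 0.0633). None of 7 erythroid genes passed limma over all probe sets or adjusted over the list alone (median -0.08, camera adjusted p = 0.743), with log2 fold changes of 0.47 for Alas2 and -0.37 for Gata1.

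Of 27 measured proliferation genes 1 passed. This was Cdc20, a mitotic regulator, which fell by 0.53 on the log2 scale, and adjusted over the list alone 7 fell. The median was -0.21 (camera adjusted p = 2.44e-05, adjusted p = 0.422 with an estimated correlation). Cdc20 lost its call without any 1 of the arrays (adjusted p = 0.0549 to 0.133). Of 14 genes of cell cycle exit and p53 response, the inhibitors Cdkn2b and Cdkn1a rose by 1.42 and 1.37 and Trp53inp1 by 1.05, Perp fell by 1.07 and 10 did not pass (median 0.04, camera adjusted p = 0.368). The list passed with fry by direction (adjusted p = 0.00301), the lowest of 16 alternatives, and Perp lost its call without the filter (adjusted p = 0.0506) or the variance trend (adjusted p = 0.0505). Adjusted over the list alone 3 rose and 2 fell, and Cdkn2b lost its call without mutant replicate 1 (adjusted p = 0.0520).

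Immediate early and stress genes rose more often than they fell, and hypoxia and glycolysis genes went both ways. Fosb, Jun and Ier3 rose by 1.27, 0.89 and 0.62, Dusp1, chosen after its values were seen, by 0.52, and the heat shock gene Hspa1b fell by 1.07. Of 18 measured stress genes 13 did not pass, and adjusted over the list alone 8 rose and 3 fell (median 0.32, camera adjusted p = 0.0334, adjusted p = 0.488 with an estimated correlation). The list's call ended without control replicate 1 (adjusted p = 0.214) and without mutant replicate 1 (adjusted p = 0.110), with a range of 0.00644 to 0.488 over 16 alternatives, and without mutant replicate 1 its median was 0.09. Fosb lost its call without control replicate 2 (adjusted p = 0.0590) or mutant replicate 1 (adjusted p = 0.119), Ier3 without control replicate 2 (adjusted p = 0.0770) or mutant replicate 2 (adjusted p = 0.150), and Hspa1b without mutant replicate 1 (adjusted p = 0.0552), the filter (adjusted p = 0.0714) or the trend (adjusted p = 0.0704). Dusp1 lost it without control replicate 2 (adjusted p = 0.108), mutant replicate 1 (adjusted p = 0.213) or mutant replicate 2 (adjusted p = 0.0859). Of 14 hypoxia and glycolysis genes Adm and Bnip3 rose by 1.48 and 1.16, Slc2a1 and Pdk1 fell by 1.03 and 0.73 and 10 did not pass. Adjusted over the list alone 2 rose and 3 fell (median 0.10, camera adjusted p = 0.711). Adm and Pdk1 lost their calls without mutant replicate 2 (adjusted p = 0.0731 and 0.0990).

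The deposited list of changed genes was compared with the signal values of the same arrays. The list holds 170 probe sets, 121 higher and 49 lower in mutant skin, and was chosen by the authors on these samples, so it is not independent evidence of direction. All 170 had the listed direction in the signal values, and of the 150 that were tested 117 (78%) passed limma. Another 1466 probe sets passed limma and are not in the list, 855 of them changed at least 2-fold. Of the 12 genes with the largest fall only Irx2 and Rspo1 are in the list. Krt1, Krt10 and Krt77 are absent from it, so the agreement does not cover their fall. The lower probe sets of the list include an array control for 18S RNA. Across probe sets, which are not independent, the listed and the measured log2 ratios correlated with r = 0.982 (Spearman rho 0.961), with a median absolute difference of 0.768, and the listed change was the larger for all 170. Without the offset, which shrinks changes of dim genes, the median absolute difference was 0.562 and the listed change the larger for 158. Of the list's own 4 columns of normalized values, the mutant to control ratio lay on the listed side beyond 1.5-fold for 95 probe sets, within 1.5-fold of no change for 63 and beyond 1.5-fold on the other side for 12.

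**Figure D4:**
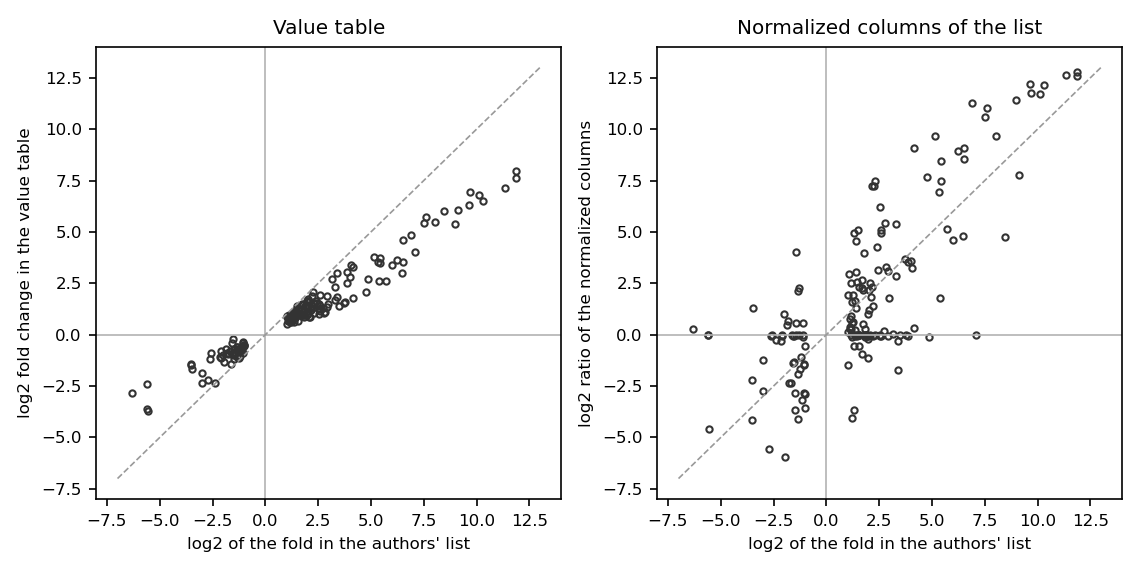
For the 170 listed probe sets (1 circle each), the log2 fold listed by the authors (x axis) and the log2 ratio of mutant to control (y axis) from the signal values (left) and from the list's own normalized columns (right), with a dashed line of equality. The signal values give the listed direction for all 170, and the normalized columns lie beyond 1.5-fold on the listed side for 95.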

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

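All tests in this part were chosen after the results were seen. Outside the tested probe sets, 3 array control probe sets read higher in both mutant arrays than in both controls. The probe set for the mouse B1 repeat was higher by 0.49 on the log2 scale, with signals of 2361 and 1868 in the controls and 2871 and 3043 in the mutants. The 3' probe set of the transferrin receptor control was higher by 0.54 on the log2 scale (108 and 92.0 in the controls, 148 and 148 in the mutants). The 5' probe set of the same control was higher by 0.57 on the log2 scale (38.7 and 26.4 in the controls, 54.3 and 48.9 in the mutants).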

How the results depend on the processing

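All alternatives reported here were planned, and none reversed a call. Of the comparisons of list calls under alternatives, 376 stayed on their side of the threshold, 33 lost and 3 gained a call; for named genes these counts are 1940, 167 and 12. Besides losses by leaving out arrays, 38 of these gene calls ended without the filter (adjusted p up to 0.115; Actg2, Adm, Bmpr1b, C1qa, Cdc20, Cdh1, Col11a1, Dct, Dusp1, Eda, Etv4, Fbln2, Fgf20, Flt4, Fosb, Gas1, Hoxa9, Hspa1b, Ier3, Isl1, Jag2, Krt15, Krt23, Ltb, Lyz2, Myh3, Myh7, Nkd2, Nrp2, Pdk1, Perp, Pmel, Ramp2, S100b, Tbx18, Tnfrsf19, Ttn and Wnt3a). Without the variance trend 25 ended (adjusted p up to 0.105), 23 of them in that list besides Hoxb3 and Prrx1, and with a robust trend 6 (adjusted p up to 0.252; Col11a1, Krt15, Krt23, Myh3, Myh7 and Ttn). The mean of probe sets ended 6 (Cdc20, Col11a1, Eda, Hoxa9, Pdk1 and Wnt3a, up to 0.165), no offset 6 (Col11a1, Fgf20, Gas1, Krt23, Ramp2 and Wnt3a, up to 0.0709), and quantile normalization 3 (Etv4, Fgf20 and Wnt3a, up to 0.0621). Without the filter 880 probe sets passed (557 higher, 323 lower), of 45037 tested, for which the cause was not tested. With the filter at the percentile 75 of signal 828 passed (469 higher, 359 lower), since fewer were tested: of 846 called probe sets that were still tested, 808 stayed called. An adjusted p under 0.10 gave 2686 and an added 2-fold limit 951, by their construction. Leaving out 1 array gave 982 to 2171 probe sets, 546 to 1323 higher and 406 to 848 lower, and 14 to 16 lists; the highest counts of probe sets came without control replicate 1, and the cause was not tested. The other alternatives gave 1198 to 1709 probe sets.

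The labels number the samples 1 and 2 in each group. With that number as a block, 2443 probe sets passed (1065 lower), all 1583 among them, and so did Krt14 (adjusted p = 0.00146), Krt5 (adjusted p = 0.00341) and Col2a1 (adjusted p = 0.0207), while no list call changed. Nothing in the labels pairs the embryos, and the deviations of same-numbered arrays correlate with r = 0.155 across probe sets. Array 1 exceeded array 2 in both groups in the hybridization spikes, by 0.46 and 0.47 on the log2 scale, and in mean signal, 227 against 220 in the controls and 227 against 219 in the mutants. The log2 ratio of 3' to 5' Gapdh was -0.52 and -0.39 in the controls and -0.51 and -0.42 in the mutants. A handling step shared by number is thus not excluded, and the block is the only fit run that allows for one; the cause of its higher count was not tested. The planned batch block was not run, as the files name no batch other than a day shared by all 4 arrays.

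With an estimated correlation camera called 0 of 26 lists (2 at an unadjusted p under 0.05, lowest adjusted p 0.164), where the correlation rests on 4 arrays. The fry test, which does not compare a list with other genes, called 9 lists by direction and 24 in either direction. By direction it did not call Wnt targets (adjusted p = 0.114), epidermal differentiation (0.140), basal epidermis (0.154), Eda (0.0747), melanocyte (0.114), muscle (0.153), macrophage and mast cell (0.0620), cartilage (0.140) and stress genes (0.130), and it added endothelium (0.0451) and cell cycle exit (0.00301); the cause of these differences was not tested. Signals near the offset of 7.7 limit the folds of the hair keratins.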

Other observations

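The gene families, their counts and all tests in this part were chosen after the results were seen, apart from the comparison of cell classes in the authors' list, which was fixed before its result was seen. All 5 measured Irx genes, homeobox transcription factors, fell: Irx2 by 3.71, Irx1 by 2.44, Irx3 by 2.37, Irx5 by 1.96 and Irx4 by 1.86 on the log2 scale. In the HoxC cluster Hoxc5 and Hoxc8 fell by 2.10 and 1.28 and Hoxc4 from a mean signal of 505 to 214, while Hoxc13, a regulator of hair keratins, rose from 7.67 to 159, and 3 of 7 did not pass. In the HoxA cluster 3 of 6 genes fell, Hoxa7 by 2.21, Hoxa5 by 1.32 and Hoxa9 by 0.70, in the HoxD cluster 1 of 3, Hoxd8 by 0.90, and in the HoxB cluster 2 of 6 rose, Hoxb6 by 1.10 and Hoxb3 by 0.64. Hoxa9 lost its call without control replicate 1 (adjusted p = 0.0901), mutant replicate 1 (adjusted p = 0.0651) or mutant replicate 2 (adjusted p = 0.181), and over 14 alternatives its adjusted p ran from 0.0186 to 0.181. Hoxb6 lost its call without mutant replicate 1 (adjusted p = 0.0649) or mutant replicate 2 (adjusted p = 0.0734), and Hoxb3 without control replicate 2 (adjusted p = 0.0563), mutant replicate 1 (adjusted p = 0.119) or mutant replicate 2 (adjusted p = 0.114).

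Of 3 measured Dlx genes Dlx2 rose by 3.47 and Dlx3 by 2.42. Their control means, 17.8 and 16.5, lay under the filter of 31.1, so both were tested only because of their mutant signals. Of 21 tested keratin-associated protein genes 20 rose, from control signals mostly near or under the offset, so no size is given. Those 20 had control means under the filter of 31.1 and were tested only because of their mutant signals. Members dim in both groups were not tested, so the share that rose was set largely by the filter. The netrin receptors Unc5b and Unc5c rose by 1.94 and 2.62. Of 5 smooth muscle genes Tagln, Actg2 and Mylk rose by 2.07, 1.06 and 1.03, and of 9 semaphorin 3 and neuropilin genes Nrp2 rose by 0.62 and Sema3d fell by 1.02. Actg2 lost its call without control replicate 2 (adjusted p = 0.0604), mutant replicate 1 (adjusted p = 0.0700) or mutant replicate 2 (adjusted p = 0.131), and Nrp2 without control replicate 2 (adjusted p = 0.0760) or mutant replicate 2 (adjusted p = 0.149). These values are of 1 probe set per gene. Among probe sets of the authors' list, others of Nrp2 rose by 1.39 and 0.94 (limma adjusted p = 0.00408 and 0.00952). One of Sema3f fell by 0.93 (limma adjusted p = 0.0214), where the Sema3f probe set used here fell by 0.29 and did not pass (limma adjusted p = 0.293). Cxcl13, a B cell attractant, rose from a mean signal of 24.9 to 264, and Vip, a neuropeptide, from 1.56 to 162, while Calb1, a calcium-binding protein, fell from 90.5 to 10.7.

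The 8 cartilage matrix genes exceeded mutant replicate 2 in mutant replicate 1 by a median log2 difference of 4.14, and Col9a1 read 3261 against 125, values that cartilage tissue in that sample would give. Acan, Matn1, Matn3 and Comp read under the filter of 31.1 in the other arrays, so they were tested only through mutant replicate 1. The same cartilage as the source of Ibsp and Sp7 is argued against, because their larger difference between the mutants, 1.19, lies under the lowest of the 8, 1.77. Both genes were also higher in mutant replicate 2 than in the control mean, by at least 2.18 on the log2 scale. The 8 cartilage genes were higher there too, but by less, from 0.05 for Comp to 1.99 for Col11a1. A candidate explanation is the genotype, but bone tissue in both mutant samples cannot be told apart from it, because both would set the mutants apart from the controls.

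The lower Irx and HoxC transcripts may follow from what the skin samples held. A lower share of epidermal cells as the whole cause would lower the 22 basal keratinocyte genes as much as the 5 Irx genes. The median of Irx genes lay under that of basal genes by a difference of -1.66, against an SD of 0.866 among basal genes. Of the 22, 2 fell as far as the least lowered Irx gene. The Irx genes were chosen after their fall was seen, so this comparison cannot decide, and a lower share stays open. It also did not cover HoxC genes, whose median over paralog groups 4 to 9 was -1.20, against -0.71 for basal genes. Trunk skin missing from the mutants would lower HoxB and HoxC genes of paralog groups 4 to 9 alike. The HoxB median, 0.51, lay 1.71 above the HoxC median, which goes against this. Both clusters were chosen after their values were seen and only 1 of 4 HoxB genes passed, so missing trunk skin stays open. Loss of the differentiating layers, where Krt1 and Krt10 fell, stays open and was not tested, as does an effect of beta-catenin on these genes.

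The normalized columns of the authors' list do not give its fold column. Compression of dim probe sets by GCRMA would leave no reversed probe sets, but 12 lay beyond 1.5-fold on the other side of the listed fold. It is thus argued against as the whole cause, but stays open for the 63 flat probe sets. Some of these had nearly the same column ratio, such as Adipoq (0.982), Alpl (0.982) and Calb1 (0.980). Shuffled table lines would leave no relation, but Spearman's rho was 0.655 across listed probe sets (permutation p = 1e-05, the smallest that 100000 permutations can give). Members of mesenchymal and blood lists were flat or reversed in 4 of 6 cases and members of epithelial lists in 0 of 12, a difference of 66.7 percentage points (Fisher's exact test, p = 0.0049). That test takes genes as independent. All epithelial members except Shh belong to the hair shaft and matrix list, whose genes rose together, so the p-value overstates the evidence. Columns measured on samples that held little dermis would give such a split between the classes, as for Adipoq, with a listed fold of 135 and a column ratio of 0.982. Lpl, 1 of the 4, was reversed, with a listed fold of 2.33 and a column ratio of 0.0607. Little dermis would flatten a ratio but not reverse it, so it does not account for Lpl or for the other reversed probe sets. For flat probe sets such as Adipoq, compression would also give a ratio near 1, so these causes cannot be told apart there. The epithelial members also have the larger listed folds, which leaves the size of the change open as a further reason.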
